A study of Homo sapiens with 12 samples.

How the data were processed

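RNA of 12 cultures of HK-2 cells, a human proximal tubular cell line, was measured on Affymetrix arrays. There were 3 arrays in each of 4 groups: Fk and control vehicle, each at 12 h and 48 h. Per the labels, cells were seeded 24 h before treatment at 700000 cells per well in 2 ml of medium with 5 mM glucose and were about 90% confluent, and the total RNA was labelled as biotin cRNA. The labels call the arrays of a group biological replicates. The deposited values are GCRMA values per probe set, per the submitters' processing notes, and they are on the log2 scale by their range. GCRMA adjusts background from probe sequence, normalizes quantiles between arrays and summarises each probe set. Its version, and whether these arrays were normalized together or with others, are not stated in the sources used here.

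The table holds 54675 probe sets, of which 41097 carry 1 gene symbol, 1801 several and 11777 none. Each gene was represented by its brightest probe set among those with 1 symbol, and a gene was tested if this probe set reached a log2 value of 4 on at least 3 arrays. That left 10784 of 19775 genes. Upper quartiles of the arrays ran from 6.90 to 7.16.

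Gene tests used limma 3.58.1 in R 4.3.3, with a mean per group over all 12 arrays, moderated by eBayes (8 residual and 2.44 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold at an adjusted p of 0.05. The contrasts were Fk minus control at 12 h and at 48 h, the difference and the mean of these effects, and control at 48 h minus 12 h. Intervals are 95% confidence intervals of limma. Lists of genes, 36 in number and covering kidney cell types, injury, stress, metabolism, cell cycle and signalling, were tested with camera at a preset correlation of 0.01 between genes where at least 5 members were tested, which held for 33. Camera was repeated with an estimated correlation, and fry, which tests whether the genes of a list move on balance in one direction, was run beside it. P-values of list members were also adjusted over the list alone. Quality measures of the control probe sets were compared by an exact two-sided permutation test within times, with 400 assignments and a smallest possible p of 0.005.

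The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named, at each time, the 10 largest rises and falls past the threshold without overlap of the arrays, or, where none passed, the 3 genes with the smallest p in that direction, up to 4 members with the smallest adjusted p from each called list, and 13 genes always. A gene of these 13 and a quality measure are not reported here. For the other contrasts it named the 5 largest rises and falls, or again 3 where none passed. Members of lists named in the control time course were added after the results were seen.

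In all, 31 settings beside the reported one were tried, 27 planned and 4 added after seeing the data. Of these, 12 left out a single array. The others changed the filter, the choice of probe set, the normalization, the moderation, the weights of the arrays, a block for the replicate number, the thresholds, the list test, the arrays in the fit or a covariate. The added ones were the poly-A spike-in level as a covariate and fits that combined a block or a restriction to the groups compared with each other or with leaving out Fk_12h replicate 3. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

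The gene test was checked on 10 simulated sets of 10784 genes with 200 changed, 100 by 1 log2 unit and 100 by 2. At 12 h it recovered 58.5% and 89% of them, at 48 h 59% and 89.1%, and over both times 79.6% and 97.2%, with 6.7, 8.8 and 10.9 false calls per set. These sets held independent normal noise with the same SD of a gene on every array. They held no outlying array and no spread shared between arrays, so the shares recovered may not hold for the real arrays. In simulations with independent genes, camera called 3 lists without change in total over 10 sets of 33 lists, and a list shifted by 0.5 was called in 10 of 10. These sets held no genes that move together, so they do not show how often camera calls a real list by chance. Other splits of the real arrays gave up to 10 called lists at 12 h and 13 at 48 h.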

Results

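Gene expression was measured in HK-2 cells, an immortalized line of human renal proximal tubular epithelial cells, after 12 h or 48 h with the treatment that the labels call Fk or with its control vehicle. The labels do not expand this name, and a dose was not used here. Each of the 4 groups held 3 arrays, 12 in all, and the labels call the arrays of a group biological replicates. The array medians ran from 2.85 to 2.94 on the log2 scale. The number of arrays limits the precision: the 95% interval of a gene's Fk effect had a median half-width of 0.447 log2 units at each time. The comparisons ask what Fk did to the cells at each time, what it did at both, and how the control cultures themselves differed between the times.

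Time in culture separated the arrays along the first principal component, which held 55.4% of the variance. The second component, with 19.4%, set Fk_12h replicate 3 (score 66.4) apart from every other array. On this array 569 genes lay more than 1 log2 unit above the mean of Fk_12h replicates 1 and 2 and 1091 lay as far below, whereas 72 genes differed that much between replicates 1 and 2. Genes that growth factor and inflammatory signals switch on within minutes to hours moved both ways on it. Several were low, while NR4A2 and RGS2 (+3.70) were high. DUSP6, a phosphatase that limits ERK signalling, deviated by -4.46, the chemokine gene CXCL8 by -4.43 and the cytokine gene IL6 by -4.17, to 3.57, under the level of 4 set for testing, while the nuclear receptor gene NR4A2 deviated by +4.61, from a level of 2.94 not shown to be above background, and ADM, which encodes adrenomedullin, by +3.97. These genes were chosen after their values were seen. The immediate early and MAPK feedback list had a median deviation of -1.57 on this array and the TGF-beta response list one of -0.98, both below all of 10000 random lists of the same size. The array's signal for a 28S ribosomal RNA control probe set was 14.38, against 8.50 to 10.29 on the others, and it correlated with its own group at 0.942 to 0.946, against 0.994 between replicates 1 and 2. Several Fk results are therefore also given without this array.

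**Figure D1:**
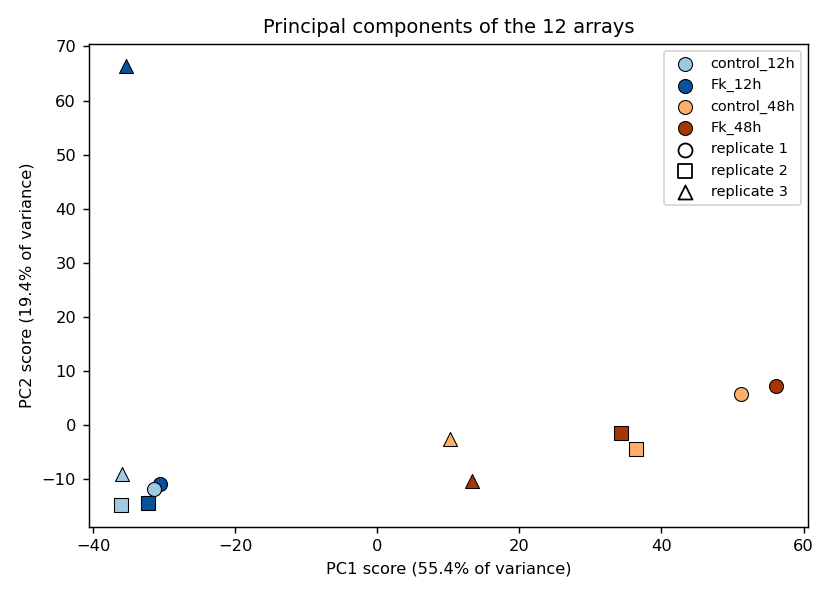
Scores of the 12 arrays on the first and second principal components of the log2 values of 10784 genes, with colours for the 4 groups and circles, squares and triangles for replicates 1, 2 and 3. The 12 h and 48 h arrays part along the first axis (55.4% of the variance), and Fk_12h replicate 3 stands alone at 66.4 on the second.

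At 12 h, camera with its preset correlation called 6 gene lists, of amino acid stress, ribosome production, inflammation, the interferon response, hypoxia and respiration. With an estimated correlation it called 0, and so did fry, and 0 members passed when adjusted over all genes. Among ATF4 targets, which the integrated stress response switches on, 27 of 29 measured genes had a positive log2 fold change. The median was +0.43 (camera adjusted p = 1.8e-07; adjusted p = 0.728 with an estimated correlation). PHGDH and PSPH, enzymes of serine synthesis, had values of +0.89 ± 0.22 (SE, n = 3 per group) and +0.67 ± 0.20, the mitochondrial folate enzyme MTHFD2 +0.42 ± 0.15, and CHAC1, which breaks down glutathione, +2.11 ± 0.77, or +1.21 without Fk_12h replicate 3. The ATF4 median was +0.72 without Fk_12h replicate 2 and +0.35 without Fk_12h replicate 3, on which the list had deviated by +0.44. Of the ribosome biogenesis and MYC target genes, 25 of 26 were negative. The median was -0.29 (adjusted p = 2.2e-08; adjusted p = 0.517 with an estimated correlation). Examples were the ribosome assembly factors NOP16 at -0.59 ± 0.14, NOP14 at -0.46 ± 0.14 and BYSL at -0.56 ± 0.19, and the RNA polymerase I subunit gene POLR1B at -0.54 ± 0.22. Without Fk_12h replicate 3, BYSL stood at -0.37 and POLR1B at -0.25.

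In the NF-kB and inflammatory cytokine list, 18 of 20 genes were negative at 12 h. The median was -0.27 (camera adjusted p = 6.3e-04; adjusted p = 0.728 with an estimated correlation), or -0.17 without Fk_12h replicate 3. The neutrophil chemokine genes CXCL2 and CXCL5 stood at -1.66 ± 0.54 and -0.83 ± 0.44, the adhesion molecule gene VCAM1 at -1.07 ± 0.38 and IL6 at -2.61 ± 1.08. Without Fk_12h replicate 3, CXCL2 stood at -0.88, VCAM1 at -0.64 and IL6 at -1.22, and CXCL5 ran from -1.64 to -0.15 over all alternatives. Interferon response genes were positive in 19 of 22 cases. The median was +0.36 (adjusted p = 8.5e-04; adjusted p = 0.728 with an estimated correlation). OASL (+1.44 ± 0.35), IFI44 (+1.71 ± 0.48) and HERC5 (+0.55 ± 0.15), which take part in antiviral defence, passed when adjusted over the list alone, the only 3 members of the 6 called lists to do so. The interferon median was +0.23 without Fk_12h replicate 1 and +0.19 without control_12h replicate 3, and the call ended when the level of the poly-A spike-ins entered as a covariate, an alternative chosen after seeing the data (+0.06). HIF targets were positive in 17 of 20 cases. The median was +0.29 (adjusted p = 0.00782; adjusted p = 0.728 with an estimated correlation). Members include KDM3A, a histone demethylase, at +0.58 ± 0.28 and PDK1, which holds back pyruvate oxidation, at +0.42 ± 0.16. Without Fk_12h replicate 3 KDM3A stood at +0.18. The HIF call ended without that array (+0.26) and without control_12h replicate 2 (+0.23). Oxidative phosphorylation subunits were negative in 26 of 33 cases. The median was -0.10 (adjusted p = 0.00989; adjusted p = 0.935 with an estimated correlation). Members include the succinate dehydrogenase gene SDHA at -0.32 ± 0.17. This call ended without Fk_12h replicate 1 (-0.06), Fk_12h replicate 2 (-0.09) or control_12h replicate 2 (-0.11), and the median was -0.16 without Fk_12h replicate 3. Leaving out Fk_12h replicate 3 gave 11 called lists in place of 6, and leaving out control_12h replicate 2 gave 4.

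Single genes at 12 h did not pass the test. SLC16A14, a member of the monocarboxylate transporter family, stood at 7.06 ± 2.28 (SD, n = 3) in Fk cultures and 2.83 ± 0.24 in control cultures, a log2 fold change of +4.23 with a 95% interval from 2.40 to 6.07 (adjusted p = 0.575). Its control arrays read 2.55 to 3.01, near the array medians and under the level of 4 set for testing, so the size of the change is taken against a signal not shown to be above background. Its Fk arrays read 5.65, 5.84 and 9.69, the last on replicate 3, and without that array the change was +2.91 with an interval from 2.54 to 3.28 (adjusted p = 1.5e-04, the smallest over the 25 alternatives, of which the largest was 0.998). The endocytosis gene FCHO2 (+0.88 ± 0.14) and the kinase gene FRK (+0.96 ± 0.17) had the smallest p-values among positive changes, and CDKN1C, a CDK inhibitor, had -1.20 ± 0.26, followed by C10orf88 at -0.54 ± 0.12 and GATD1 at -0.45 ± 0.10 (SE, adjusted p = 0.575 for all 5). Other probe sets gave smaller values, -0.61, -0.48 and -0.44 for CDKN1C and -0.066 for C10orf88. Within the list of G1 cyclins and CDK inhibitors, which was not called (adjusted p = 0.549), CDKN1C and CCNG2, a cyclin linked to growth arrest, at +0.91 ± 0.19, passed when adjusted over the list alone (adjusted p = 0.00592 for both). Without Fk_12h replicate 3, the alpha-arrestin gene ARRDC4 at +1.29 and the ankyrin repeat gene ANKRA2 at +1.38 also passed. The control arrays of ARRDC4 at 12 h read 2.81 to 3.09, under the level of 4, so the size of its change is uncertain. INHBE, which encodes an inhibin subunit, had +3.07 ± 0.65 and did not pass (adjusted p = 0.575). It was the only gene to pass at 12 h with a replicate block within time, an alternative setting. Its control arrays at 12 h ran from 2.91 to 5.67, partly under the level of 4, so the size of its change is uncertain. CCNG2, ARRDC4, ANKRA2 and INHBE were chosen after their values were seen.

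By limma, 0 of 10784 genes passed at 12 h with an adjusted p under 0.05, while 724 had an unadjusted p under 0.05, against 539.2 by chance. That number was 432 and 463 without control_12h replicates 2 and 1, below chance, and 1087 without Fk_12h replicate 2. The Fk and control arrays did not overlap for 1769 genes, or 16.4%, where chance gives 10%. The count of genes that passed was 3 without Fk_12h replicate 3 and 156 with array quality weights, which gave that array a weight of 0.121.

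**Figure D2:**
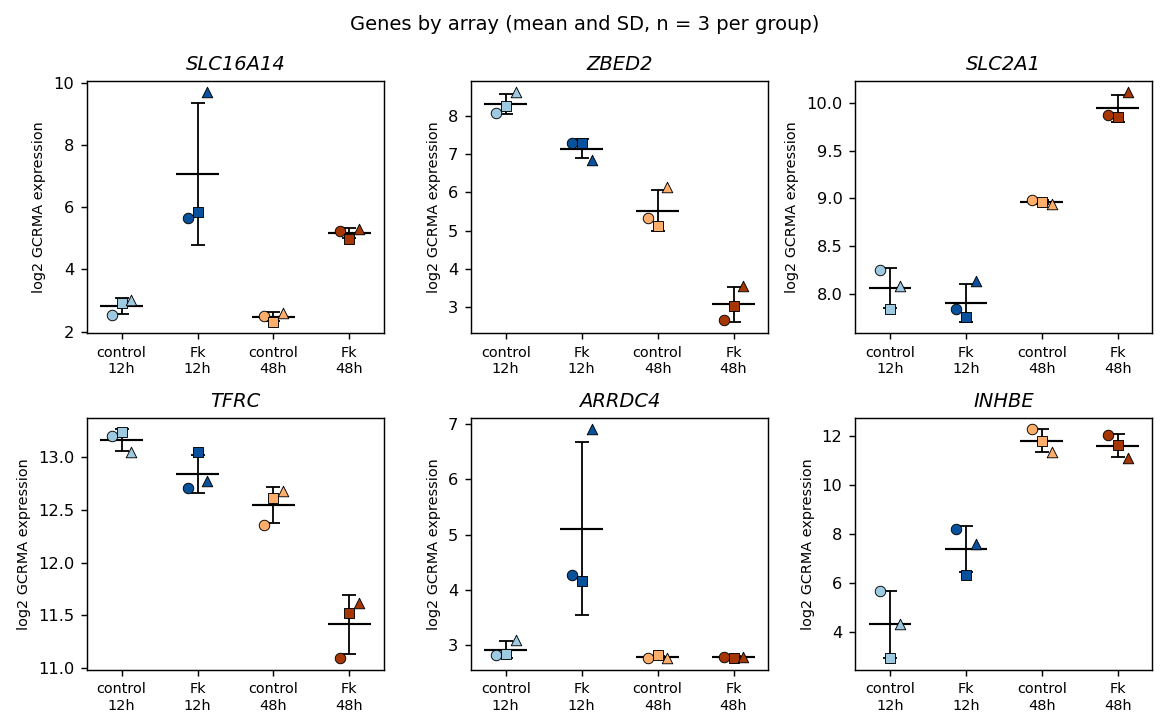
Log2 expression of SLC16A14, ZBED2, SLC2A1, TFRC, ARRDC4 and INHBE on each array of the 4 groups, with circles, squares and triangles for replicates 1, 2 and 3, horizontal bars for group means and error bars for the SD (n = 3). SLC16A14 was at 5.17 ± 0.16 in Fk and 2.48 ± 0.14 in control cultures at 48 h, and its 12 h Fk replicate 3 stands at 9.69.

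At 48 h, camera with its preset correlation called 8 gene lists, with negative medians for cholesterol synthesis and positive ones for glucose use, hypoxia and TGF-beta signalling among them. With an estimated correlation it called 0, and so did fry by direction, and 0 members passed when adjusted over all genes. On the first principal component, replicates 1 at 48 h lay at one end in both groups (56.1 in Fk and 51.2 in control). Replicates 3 lay at the other end (13.3 and 10.2). Leaving out such an array therefore also shifts the groups against each other along this axis, which parts 12 h from 48 h. In the list of cholesterol synthesis and SREBP2 targets, 18 of 19 genes were negative and 0 passed when adjusted over the list alone. The median was -0.43 (camera adjusted p = 7.3e-09; adjusted p = 0.312 with an estimated correlation). The mevalonate pathway genes MVK and MVD stood at -1.003 ± 0.32 (SE, n = 3 per group) and -0.52 ± 0.26, the acetyl-CoA thiolase gene ACAT2 at -0.75 ± 0.34 and the sterol dehydrogenase gene NSDHL at -0.47 ± 0.17. Without Fk_48h replicate 1 the median was -0.24 and ACAT2 stood at -0.41. MVD stood at -0.30 without control_48h replicate 2. HIF targets were positive in 17 of 20 cases. The median was +0.27 (adjusted p = 3.9e-06; adjusted p = 0.272 with an estimated correlation). Of these, 4 passed when adjusted over the list alone and 0 when adjusted over all genes: SLC2A1, the main glucose transporter of many cell types, at +0.98 ± 0.14, the collagen prolyl hydroxylase genes P4HA2 at +0.86 ± 0.18 and P4HA1 at +0.82 ± 0.21, and NDRG1 at +1.02 ± 0.30. Glycolysis genes were positive in 19 of 20 cases. The median was +0.21 (adjusted p = 2.4e-05; adjusted p = 0.617 with an estimated correlation), and only SLC2A1 passed when adjusted over the list alone. PDK1 stood at +0.48 ± 0.16, the enolase gene ENO2 at +0.53 ± 0.24 and the aldolase gene ALDOA at +0.31 ± 0.15. Without Fk_48h replicate 3, PDK1 stood at +0.32 and ENO2 at +0.35, and ALDOA stood at +0.18 and +0.48 without control_48h replicates 2 and 3. The glycolysis median was +0.13 without control_48h replicate 1, and the call ended without Fk_48h replicate 3 (+0.09).

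TGF-beta response genes were positive at 48 h in 19 of 23 cases. The median was +0.45 (camera adjusted p = 2.7e-05; adjusted p = 0.617 with an estimated correlation). LTBP3 (+0.77 ± 0.20) and LTBP2 (+0.995 ± 0.31), of the latent TGF-beta binding protein family, the feedback inhibitor gene PMEPA1 (+0.90 ± 0.27) and TGFBI (+0.78 ± 0.24), a TGF-beta induced matrix protein gene, passed when adjusted over the list alone, 4 in all, against 0 adjusted over all genes. The median was +0.22 without control_48h replicate 1, and without Fk_48h replicate 3 the call ended (+0.18). Extracellular matrix and remodelling genes were positive in 20 of 24 cases. The median was +0.22 (adjusted p = 0.00209; adjusted p = 0.656 with an estimated correlation). The urokinase receptor gene PLAUR stood at +1.19 ± 0.41, its ligand gene PLAU at +0.90 ± 0.37 and the collagen gene COL6A2 at +0.60 ± 0.20, with PLAUR at +0.71 without Fk_48h replicate 3. This call ended without Fk_48h replicate 3 (+0.04) and without control_48h replicate 1 (+0.13), and the median was +0.39 without Fk_48h replicate 1 and +0.34 without control_48h replicate 3. Heat shock protein genes were negative in 15 of 18 cases. The median was -0.14 (adjusted p = 4.3e-04; adjusted p = 0.272 with an estimated correlation). Members include the chaperone genes HSPH1 at -0.42 ± 0.15, or -0.27 without control_48h replicate 2, and DNAJB6 at -0.50 ± 0.24.

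DNA replication genes were negative at 48 h in 31 of 35 cases. The median was -0.21 (camera adjusted p = 4.4e-04; adjusted p = 0.832 with an estimated correlation). Members include the flap endonuclease gene FEN1 at -0.41 ± 0.23 and the thymidine kinase gene TK1 at -0.56 ± 0.36. Without Fk_48h replicate 1 FEN1 stood at -0.25 and TK1 at -0.15, and TK1 stood at -1.02 without Fk_48h replicate 3 and -0.33 without control_48h replicate 3. The DNA replication median turned to +0.12 without Fk_48h replicate 1 and to +0.03 without control_48h replicate 3, where the call ended, and it was -0.43 without Fk_48h replicate 3 or control_48h replicate 1. In control cultures the list had a median of -1.19 at 48 h against 12 h. The imbalance of replicates 1 and 3 named above would therefore move it in these directions, whatever Fk did. The DNA replication median also turned slightly positive with the level of the poly-A spike-ins as a covariate, an alternative chosen after seeing the data. Probe sets of 1 member, RFC5, differed in sign: its brightest gave -0.38 ± 0.26 and the mean of its probe sets +0.10. Metallothioneins and metal response genes were positive in 10 of 11 cases. The median was +0.35 (adjusted p = 0.0433; adjusted p = 0.813 with an estimated correlation). Members include the metal-binding MT1X at +0.59 ± 0.39, which stood at +0.96 without Fk_48h replicate 1, +0.24 without Fk_48h replicate 3, +0.33 without control_48h replicate 2 and +1.03 without control_48h replicate 3. The metallothionein call ended when any of 7 single arrays was left out. The median was then +0.14 without Fk_48h replicate 3, +0.24 without control_48h replicate 1, +0.17 without control_48h replicate 2, and +0.35 without Fk_12h replicate 2 or 3 or control_12h replicate 2 or 3. The metallothionein median was +0.69 without Fk_48h replicate 1 and +0.71 without control_48h replicate 3, and the call also ended without the probe sets that can bind several transcripts (+0.15).

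Among single genes at 48 h, ZBED2, a zinc finger gene, stood at 3.07 ± 0.45 (SD, n = 3) in Fk and 5.52 ± 0.54 in control cultures, a log2 fold change of -2.45 with a 95% interval from -3.11 to -1.80 (adjusted p = 0.0724). Its Fk arrays at 48 h, at 2.65 to 3.55, lay near the array medians and under the level of 4, so the size of this change is uncertain. SLC2A1 stood at 9.95 ± 0.14 against 8.96 ± 0.02, and TFRC, the transferrin receptor gene, at 11.41 ± 0.28 against 12.55 ± 0.17, a change of -1.13 with an interval from -1.50 to -0.77 (adjusted p = 0.0976 for both). AXIN1, a scaffold of the Wnt pathway, had +0.82 ± 0.12 (SE, adjusted p = 0.0976), ATP6V0D2, a proton pump subunit gene, +2.02 ± 0.33 (adjusted p = 0.148), and CYTL1 -0.73 ± 0.11 (adjusted p = 0.114). SLC16A14 stood at 5.17 ± 0.16 against 2.48 ± 0.14 (SD), a change of +2.69 whose interval from 0.86 to 4.53 carries the spread of Fk_12h replicate 3 (adjusted p = 0.692). Without that array the interval was 2.36 to 3.02 and SLC16A14, named here after its value was seen, passed. The control signals of SLC16A14 and ATP6V0D2 (2.97 ± 0.54) also lay under the level of 4 and were not shown to be above background. Of the 5 probe sets of TFRC, 3 had values from -1.13 to -1.02, another +0.18 and a dim one -0.01.

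By limma, 0 of 10784 genes passed at 48 h, while 559 had an unadjusted p under 0.05, against 539.2 by chance. For 1096 genes, or 10.2%, Fk and control arrays did not overlap, where chance gives 10% if the arrays of that time are interchangeable. Same-numbered replicates 1 and 3 deviated together (correlations of 0.798 and 0.606), so chance may give a lower share here. With a replicate block within time 983 genes had an unadjusted p under 0.05 and 0 passed. A block in a fit to the 48 h groups alone gave 1300 such genes and 1 that passed, SLC16A14. The number with an unadjusted p under 0.05 was 905 without Fk_12h replicate 3 and 349 without control_48h replicate 2. The count of genes that passed was 1 without Fk_12h replicate 3 (SLC16A14), 1 without Fk_48h replicate 1 (ATP6V0D2), 1 without Fk_48h replicate 2 (NCOA5, chosen after its value was seen) and 94 with array quality weights. At 48 h these weights were 3.62 and 1.84 for replicates 2 of Fk and control, and 0.400 to 0.624 for replicates 1 and 3. The count of 94 therefore rests mostly on replicates 2. Leaving out Fk_48h replicate 1 gave 12 called lists in place of 8.

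**Figure D3:**
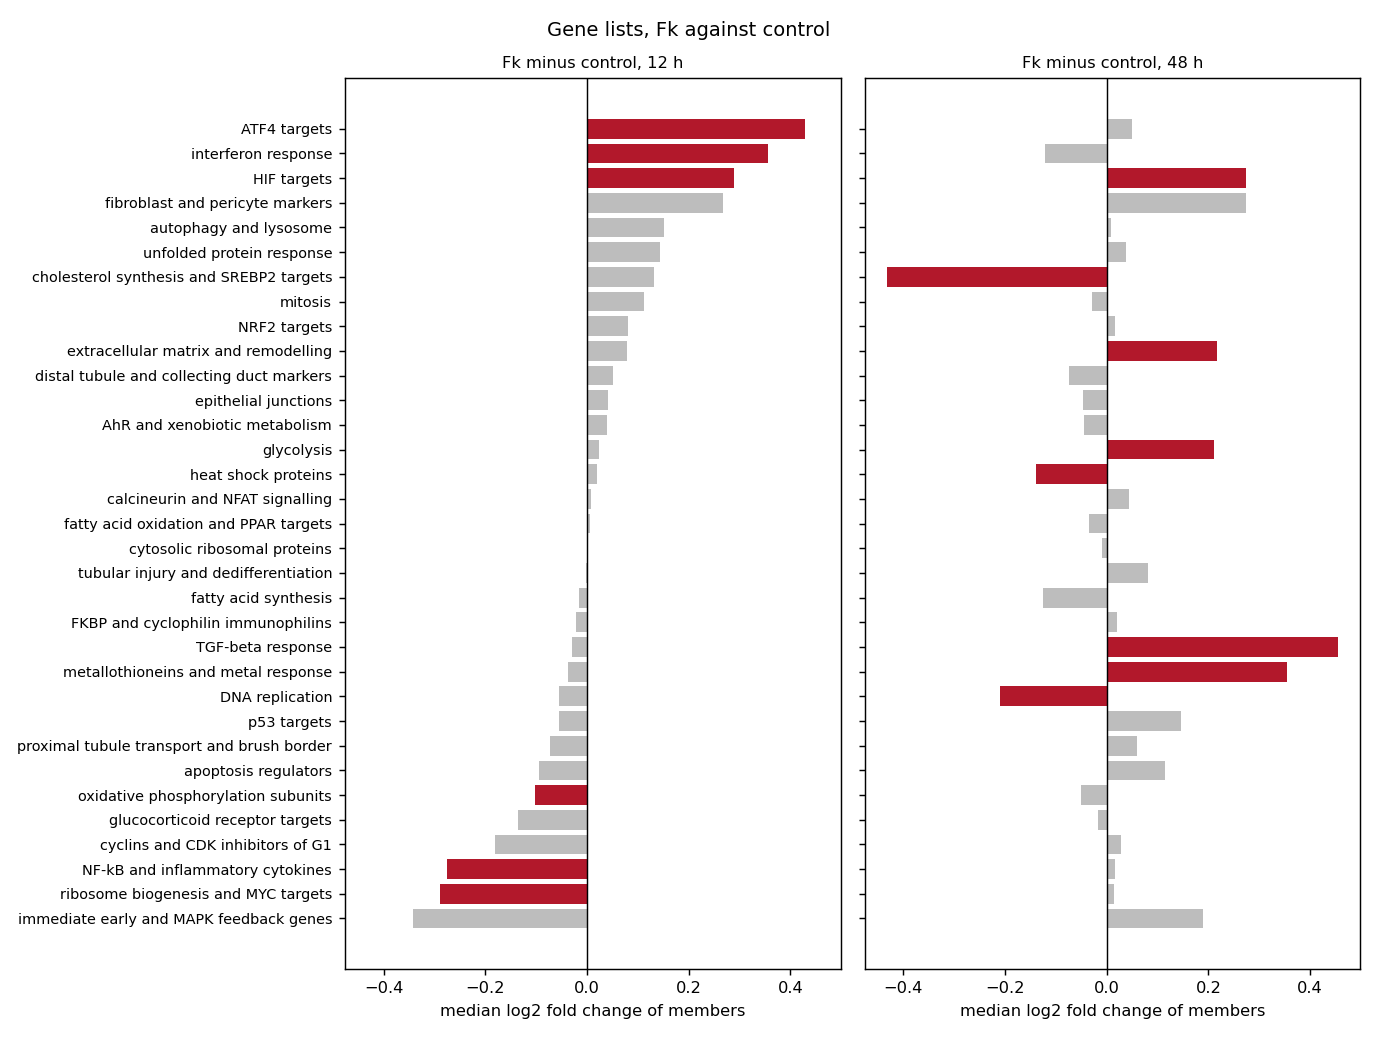
Median log2 fold change of each tested gene list, Fk minus control, at 12 h and at 48 h on a shared axis, with red bars for lists past the camera threshold (6 at 12 h and 8 at 48 h) and grey bars for the others. Among lists past the threshold, ATF4 targets (+0.43) and ribosome biogenesis and MYC targets (-0.29) have the highest and lowest medians at 12 h, and TGF-beta response (+0.45) and cholesterol synthesis genes (-0.43) at 48 h.

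Over both times together, ZBED2 was the only gene that passed. It fell by 1.81 on the log2 scale (SE 0.21, 95% interval from -2.28 to -1.35, limma adjusted p = 0.0479), and it was lower in 6 of 6 Fk arrays than on any control array of the same time. The call ended without any single array except Fk_48h replicate 3, with adjusted p-values from 0.0406 to 0.230 over the 12 arrays left out in turn and from 0.00102 to 0.561 over all 24 alternatives. SLC16A14 had +3.46 with an interval from 2.16 to 4.76 (adjusted p = 0.226), and without Fk_12h replicate 3 it passed at +2.80, as did ARRDC4, while ZBED2 (-1.74) did not. At 48 h ARRDC4 stood at 2.77 ± 0.01 in Fk and 2.78 ± 0.02 in control cultures (SD). These arrays lay under the level of 4, where a change may not show. Its difference between the times did not pass either (limma adjusted p = 0.996), so an effect at 12 h alone is not shown. The choline transporter gene SLC44A2 stood at +1.09 ± 0.16 (SE) and EVC, a cilium gene of hedgehog signalling, at +0.76 ± 0.11 (adjusted p = 0.150 for both). An unadjusted p under 0.05 was found for 856 genes, and array quality weights gave 527 genes past the threshold.

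HIF targets led the 10 lists called over both times, with 18 of 20 genes positive and a median of +0.38 (camera adjusted p = 2.8e-06; adjusted p = 0.459 with an estimated correlation), or +0.22 without Fk_12h replicate 3. In that list SLC2A1, P4HA1, P4HA2, PDK1, NDRG1 and the oxidoreductase gene ERO1A passed when adjusted over the list alone, 6 in all, against 0 adjusted over all genes. The other lists with positive medians were ATF4 targets (+0.27), TGF-beta response (+0.20), extracellular matrix (+0.13) and glycolysis (+0.11), and those with negative medians were NF-kB genes (-0.17), cholesterol synthesis (-0.14), ribosome biogenesis (-0.13), DNA replication (-0.11) and oxidative phosphorylation (-0.07). With an estimated correlation 0 of the 10 passed, with adjusted p-values from 0.459 for HIF targets to 0.806 for DNA replication. The NF-kB call ended without Fk_12h replicate 3 (-0.07), and so did that of cholesterol synthesis (-0.06), while glycolysis had +0.19 and TGF-beta response +0.32.

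Between the times, camera with its preset correlation called a different Fk effect in 9 lists, against 0 with an estimated correlation, and limma in 0 single genes, where 357 genes had an unadjusted p under 0.05. The difference given for a list is the median of its members' own differences, which need not equal the difference between the medians at 12 h and 48 h. Cholesterol synthesis genes had a median of +0.13 at 12 h and -0.43 at 48 h, a difference of -0.60 (camera adjusted p = 2.1e-08; adjusted p = 0.440 with an estimated correlation), or -0.39 without Fk_48h replicate 1. ATF4 targets went from +0.43 to +0.05 (difference -0.32, adjusted p = 3.6e-05; adjusted p = 0.640 with an estimated correlation), with -0.61 without Fk_12h replicate 2 and -0.54 without control_48h replicate 3. Ribosome biogenesis genes went from -0.29 to +0.01 (difference +0.32, adjusted p = 1.2e-05; adjusted p = 0.440 with an estimated correlation). Heat shock genes went from +0.02 to -0.14 (difference -0.31, adjusted p = 2.2e-04; adjusted p = 0.233 with an estimated correlation), with -0.20 without Fk_12h replicate 3. Interferon genes went from +0.36 to -0.12 (difference -0.33, adjusted p = 7.0e-04; adjusted p = 0.640 with an estimated correlation), a call that ended without Fk_48h replicate 3 (-0.15). The median of the interferon genes was -0.59 without Fk_48h replicate 1 and -0.17 without control_48h replicate 1.

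The other 4 of these 9 lists depended on single arrays, Fk_12h replicate 3 among them. TGF-beta response genes had a difference of +0.49 (camera adjusted p = 0.00151; adjusted p = 0.760 with an estimated correlation), and the call ended without Fk_12h replicate 3 (+0.17), Fk_48h replicate 3 (+0.36) or control_48h replicate 1 (+0.38). Immediate early genes had +0.68 (adjusted p = 0.0175; adjusted p = 0.760 with an estimated correlation), and the call ended without Fk_12h replicate 3 (+0.07), Fk_48h replicate 3 (+0.56) or control_48h replicate 1 (+0.45), with values of +1.14 without Fk_12h replicate 1 and +0.45 without Fk_48h replicate 2. NF-kB genes had +0.27 (adjusted p = 0.0175; adjusted p = 0.760 with an estimated correlation), and the call ended without Fk_12h replicate 2 (+0.19), Fk_12h replicate 3 (+0.36), Fk_48h replicate 3 (+0.20), control_12h replicate 3 (+0.20) or control_48h replicate 1 (+0.26), with values of +0.44 without Fk_48h replicate 1 and +0.49 without control_12h replicate 2. Glycolysis genes had +0.10 (adjusted p = 0.0152; adjusted p = 0.760 with an estimated correlation), and the call ended without Fk_12h replicate 3 (+0.06), Fk_48h replicate 3 (+0.04), control_48h replicate 1 (+0.06) or control_48h replicate 2 (+0.03), with values of +0.17 without Fk_48h replicate 1 and +0.25 without control_48h replicate 3. The number of called lists was 14 without Fk_48h replicate 1 or control_48h replicate 3. Among single genes, SLC2A1 had the smallest p, with a difference of +1.14 ± 0.20 (SE) between -0.15 at 12 h and +0.98 at 48 h (adjusted p = 0.996), followed among positive differences by LHX6 (+1.25 ± 0.26) and AXIN1 (+0.81 ± 0.17). The negative ones were the mitochondrial transcription gene MTERF2 (-1.03 ± 0.20), WFDC21P (-1.21 ± 0.26) and JUP, the gene of the junction protein plakoglobin (-0.80 ± 0.17).

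Across the 10784 genes, the 12 h and 48 h effects had a Pearson r of 0.137 and a Spearman rho of 0.140. These contrasts share no array, genes are not independent replicates, and 24 of 100 regroupings of the arrays within each time gave a correlation as large in size. Without Fk_12h replicate 3 the values were 0.256 and 0.246, and r was 0.0623 without Fk_12h replicate 1, 0.0223 without Fk_48h replicate 1 and 0.0871 without control_48h replicate 2. By limma 0 genes were called at both times, against 7 with array quality weights and 1, SLC16A14, without Fk_12h replicate 3. Of the genes with an unadjusted p under 0.05, 51 were positive at both times, against 15.3 for independent lists of 474 and 349 genes, and 23 were negative at both, against 4.87 for lists of 250 and 210. In opposite directions, 14 were positive at 12 h and negative at 48 h, against 9.23, and 2 the reverse, against 8.09. Both tests use the same estimate of a gene's spread, so the lists are not independent and these expected counts are only a rough guide. Of 100 regroupings, the real one included, 2 gave as many as these 74 in the same direction, and the highest other gave 117. Genes shared in the same direction included the lysosomal membrane gene GPR137B (+1.08 and +0.72), the cathepsin gene CTSB (+0.59 and +0.43), the transcription factor gene KLF7 (+0.84 and +0.89) and, in the other direction, TIPARP (-0.53 and -0.46), a target of the aryl hydrocarbon receptor, and MAL (-0.40 and -0.93). These genes were chosen after their values were seen.

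The genes fixed in advance as markers of injury, stress and calcineurin or immunophilin signalling did not pass the test at either time. HAVCR1, which encodes a membrane protein shed by injured tubules, stood at -0.18 ± 0.41 (SE, n = 3 per group) at 12 h and -0.35 ± 0.41 at 48 h, and LCN2, the gene of lipocalin, at -0.16 ± 0.57 and +0.38 ± 0.57. CLU stood at +0.42 ± 0.15, with a 95% interval from 0.08 to 0.75, and at +0.03 ± 0.15, GDF15 at -0.00 ± 0.35 and +0.45 ± 0.35, and the matrix signalling gene CCN2 at +0.02 ± 0.60 and -0.03 ± 0.60. RCAN1, which calcineurin signalling induces, stood at +0.39 ± 0.36 and -0.16 ± 0.36, and the immunophilin gene FKBP5 at -0.06 ± 0.16 and -0.02 ± 0.16. The stress genes HMOX1 (+0.57 ± 0.35 and -0.04 ± 0.35), DDIT3 (+1.05 ± 0.63 and -0.10 ± 0.63) and HSPA5 (+0.45 ± 0.35 and -0.01 ± 0.35) had their higher value at 12 h, where DDIT3 stood at +0.20 without Fk_12h replicate 3. CDKN1A stood at -0.21 ± 0.27 and +0.28 ± 0.27, and CXCL8 at -1.76 ± 0.96, or -0.28 without Fk_12h replicate 3, and +0.24 ± 0.96. None of the 12 tested genes passed at either time, with adjusted p-values from 0.673 upward. As lists, calcineurin and NFAT signalling (+0.01 at 12 h and +0.04 at 48 h, camera adjusted p = 0.751 and 0.526), FKBP and cyclophilin immunophilins (-0.02 and +0.02, adjusted p = 0.931 and 0.705) and tubular injury genes (-0.00 and +0.08, adjusted p = 0.990 and 0.211) were not called. Distal tubule markers (+0.05 and -0.08, adjusted p = 0.666 and 0.138), fibroblast and pericyte markers (+0.27 and +0.27, adjusted p = 0.226 and 0.182) and proximal tubule genes (-0.07 and +0.06, adjusted p = 0.506 and 0.764) were not called either. The proximal tubule list had a mean of 0.00 at 12 h beside its negative median. NT5E, an ectoenzyme gene in the fibroblast list, had +1.49 at 48 h and passed when adjusted over the list alone (adjusted p = 0.0395); it was chosen after its value was seen. In the proximal tubule list, SLC2A1 passed at 48 h when adjusted over the list alone (adjusted p = 4.5e-04), and fry for changes in either direction called that list (adjusted p = 0.0235).

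Control cultures differed between 48 h and 12 h. Camera with its preset correlation called ATF4 targets and the unfolded protein response with positive medians, and DNA replication and mitosis with negative ones. By fry, ATF4 targets (adjusted p = 3.2e-04), DNA replication (0.00757) and mitosis (0.0412) passed, and the unfolded protein response did not (0.122). Of 29 ATF4 targets 25 rose and 1 fell (28 and 1 when adjusted over the list alone). The median was +1.79 (camera adjusted p = 1.6e-15; adjusted p = 0.215 with an estimated correlation). DDIT3, which encodes the stress factor CHOP, rose by 4.86 ± 0.63 (SE, n = 3 per group), the cystine transporter gene SLC7A11 by 3.91 ± 0.50 and the pseudokinase gene TRIB3 by 1.90 ± 0.18. Genes of the unfolded protein response had a median of +1.27 (adjusted p = 1.7e-05; adjusted p = 0.892 with an estimated correlation), +0.75 without control_48h replicate 1, and 7 of 26 rose (8 adjusted over the list alone), among them the sensor gene ERN1 (+3.64 ± 0.37) and XBP1 (+2.06 ± 0.24). Of 35 DNA replication genes 25 fell (29 adjusted over the list alone). The median was -1.19 (adjusted p = 4.1e-13; adjusted p = 0.612 with an estimated correlation). Members include CCNE1 at -2.15 ± 0.18, CCNE2 at -2.67 ± 0.26 and MCM10, a factor of replication start, at -3.20 ± 0.50. Of 35 mitosis genes 24 fell (33 adjusted over the list alone). The median was -1.15 (adjusted p = 3.3e-12; adjusted p = 0.837 with an estimated correlation). Members include the transcription factor gene FOXM1 at -1.56 ± 0.25 and the survivin gene BIRC5 at -1.69 ± 0.35.

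HIF targets rose in 7 of 20 cases in control cultures (9 adjusted over the list alone). The median was +0.65 (camera adjusted p = 0.00143; adjusted p = 0.558 with an estimated correlation). Members include the angiogenic factor gene VEGFA at +2.26 ± 0.15 and STC2 at +2.97 ± 0.45. Of 28 autophagy and lysosome genes 8 rose and 1 fell (14 and 1 adjusted over the list alone). The median was +0.45 (adjusted p = 3.0e-04; adjusted p = 0.558 with an estimated correlation). Members include the cholesterol exporter gene NPC1 at +1.36 ± 0.22 and MAP1LC3B, an autophagosome protein gene, at +1.23 ± 0.22. Of 18 heat shock genes 9 fell (11 fell and 1 rose adjusted over the list alone). The median was -0.56 (adjusted p = 1.5e-04; adjusted p = 0.215 with an estimated correlation). Members include DNAJA1 at -1.12 ± 0.11. Ribosome biogenesis genes had a median of -0.26 (adjusted p = 0.0116; adjusted p = 0.837 with an estimated correlation) and 6 of 26 fell by either adjustment, MRTO4 at -0.85 ± 0.14, but the list call ended without control_48h replicate 3 (-0.16). Metallothioneins had a median of -0.98 (adjusted p = 0.0202; adjusted p = 0.892 with an estimated correlation), with 2 of 11 fallen (8 adjusted over the list alone), and the call ended without Fk_12h replicate 3 (-0.98) or control_48h replicate 2 (-0.76). In oxidative phosphorylation, 4 of 33 genes fell and 1 rose (1 and 0 adjusted over the list alone). The median was -0.19 (adjusted p = 0.0202; adjusted p = 0.892 with an estimated correlation), a call that ended without control_48h replicate 2 (-0.11).

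The largest rise in control cultures was that of INHBE, from 4.30 ± 1.38 (SD, n = 3) to 11.82 ± 0.47, a change of +7.52 ± 0.65 (SE, limma adjusted p = 3.3e-04). Its 12 h control arrays read 5.67, 2.91 and 4.32, the second under the level of 4, so the size of the rise is uncertain. Other large rises were those of ATF3 (+5.36 ± 0.91), DDIT3, the phospholipase gene PLA1A (+4.67 ± 0.64) and CTH, an enzyme of cysteine synthesis (+4.49 ± 0.64). The 12 h level of PLA1A, 3.03 ± 0.39 (SD), lay under the level of 4, so the size of its rise is uncertain. TXNIP, a glucose-responsive inhibitor of thioredoxin, fell from 8.72 ± 0.45 to 3.54 ± 0.25 (-5.17 ± 0.60, adjusted p = 7.7e-04). Its 48 h arrays, at 3.35 to 3.82, lay under the level of 4, so the size of the fall is uncertain. NAV3 fell by 3.36 ± 0.65, to a level of 3.73 ± 1.21 (SD) with the same limit, while TNFAIP6 (-4.66 ± 1.06), SLN (-4.91 ± 1.33) and SOX9 (-3.85 ± 0.95) fell in a test that depended on single control arrays. SLN and SOX9 no longer passed without control_12h replicate 1, 2 or 3 or control_48h replicate 1 or 2, with adjusted p-values of up to 0.1002 and 0.0639, and TNFAIP6 no longer passed without control_12h replicate 3 or control_48h replicate 1 or 2 (adjusted p up to 0.0575).

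In all, 2314 of 10784 genes differed between the control groups by limma, 1142 higher and 1172 lower at 48 h, or 21.5%, and 5388 genes, or 49.96%, had arrays that did not overlap, where chance gives 10%. The count was 1290, 1166 and 1060 without control_12h replicates 1, 2 and 3, 1084 and 1138 without control_48h replicates 1 and 2, and 4920 with array quality weights.

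**Figure D4:**
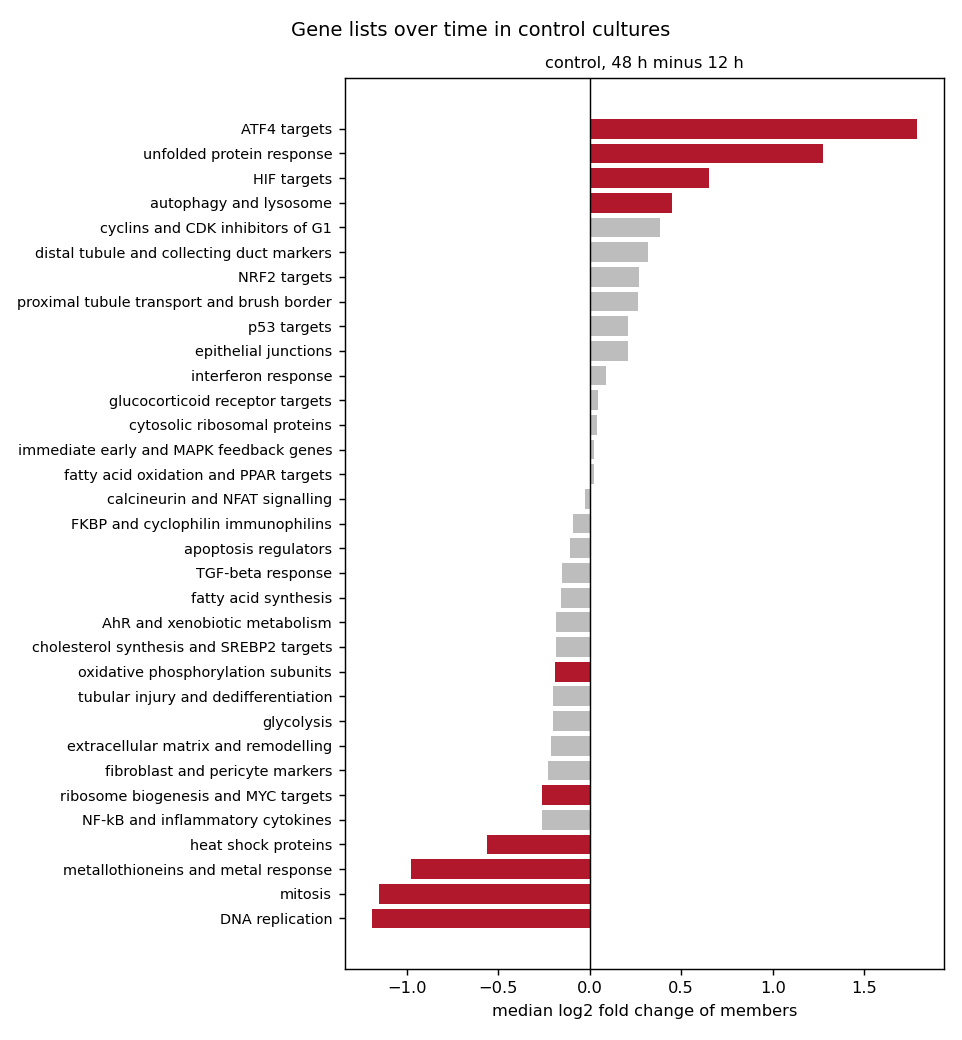
Median log2 fold change of each tested gene list between control cultures at 48 h and 12 h, with red bars for the 10 lists past the camera threshold and grey bars for the others. ATF4 targets (+1.79) and the unfolded protein response (+1.27) lie highest, and DNA replication (-1.19) and mitosis (-1.15) lowest.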

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

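Of the tests in this part, those of RNA degradation, of the change with time and of a labelling difference were chosen after the results were seen, and those of a dim array, of a stronger response and of other splits before.

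The Fk effect differed between 48 h and 12 h, by a test of the difference itself, in 9 gene lists by camera with its preset correlation, against 0 with an estimated correlation and 0 by fry. The median differences were -0.60 for cholesterol synthesis, -0.33 for the interferon response, -0.32 for ATF4 targets and -0.31 for heat shock proteins. They were +0.68 for immediate early genes, +0.49 for the TGF-beta response, +0.32 for ribosome biogenesis, +0.27 for NF-kB genes and +0.10 for glycolysis. Chance is not excluded for this count: 50 of 100 regroupings of the arrays gave as many lists, with up to 17. For single genes the count was 0 by limma, with 357 at an unadjusted p under 0.05, and 100 of 100 regroupings gave as many, with up to 1, which a count of 0 makes certain and which says nothing about chance.

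Signals outside the gene measurement differed on some arrays. The poly-A spike-ins, which are added before labelling, were higher by 0.638 on the Fk arrays (8.24 ± 0.45 against 7.60 ± 0.29, SD, n = 6 each, exact permutation p = 0.04, adjusted p = 0.21 over 6 measures). The signal of the 28S ribosomal RNA control probe set was 14.38 on Fk_12h replicate 3.

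Fk_12h replicate 3 lies apart from the other arrays, with the immediate early and TGF-beta response lists low and the ATF4 target and mitosis lists high by their medians. RNA degradation as the whole cause is argued against by its ACTB 3' minus 5' signal of 0.929, within the 0.779 to 1.02 of the other 12 h arrays. The same measure of GAPDH was 0.0064, slightly above their -0.0727 to -0.0044, so that a small part of degradation stays open. The correlation between the deviation and the level of genes was -0.0953. It cannot decide whether the array was dim, since quantile normalization between arrays evens out such a difference. The correlation between its Fk effect and that of replicates 1 and 2 was 0.0571, against 0.442 between replicates 1 and 2 themselves. This argues against a difference that is only a stronger response to Fk. Its larger deviations (SD 0.780, against 0.259 between replicates 1 and 2) lower such a correlation, so a stronger response beside them stays open. ATF4, HIF and NF-kB lists deviated on it in the direction of their 12 h medians (+0.44, +0.21 and -0.35). Interferon, oxidative phosphorylation and ribosome biogenesis lists did not (-0.12, +0.18 and +0.02). The 12 h medians include this array, so a shared direction is partly built in and weighs little for a stronger response. A difference in the handling of this culture or a wrong label was not tested and stays open.

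Among the 48 h arrays, Fk and control replicates 1 lie together, as do replicates 3. A candidate explanation is that the cultures had moved to different points along the change from 12 h to 48 h, since the difference between Fk_48h replicates 1 and 3 correlated over genes at 0.547 with the control time course. Other explanations of this grouping, technical ones included, stay open. Among the splits of the 6 arrays at 48 h, one that sets Fk and control replicates 1 and control replicate 2 against the rest gave 216 genes, where Fk against control gave 0. It parts replicates 1 from replicates 3 and splits replicates 2, and it points to a structure of the samples other than Fk.

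SLC16A14 was higher and ZBED2 lower on the Fk arrays at both times. A labelling difference that the poly-A spike-ins may mark is argued against as the whole cause. With their level as a covariate the mean effects were 3.42 (95% interval from 1.502 to 5.34) and -1.45 (from -2.01 to -0.88), against +3.46 and -1.81 without it. The labels used here name no labelling batch. At 12 h the spike-in levels parted all Fk arrays (8.20 to 8.47) from all control arrays (7.26 to 8.11). They did not do so at 48 h, where Fk_48h replicate 3 stood at 7.35, under the control arrays at 7.52 to 7.65. A labelling difference at 12 h is therefore hard to tell apart from Fk by these levels. The ZBED2 call ended with the covariate, where its effect was smaller. An effect of Fk on these genes may be the source and remains a hypothesis.

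Other splits of the arrays were counted for each result. Over both times, 4 of 100 regroupings gave as many genes as the 1 found, the real one included, a share under 0.05. The highest of the others was also 1, so that a count this small weighs little against chance. For comparisons within 6 arrays the 10 splits are too few for a share under 0.05, and a count of 0 is reached by every split and tests nothing. At 12 h, 10 of 10 splits gave as many genes as the 0 found (highest other 1) and 4 of 10 as many lists as the 6 (highest other 10). At 48 h, 10 of 10 gave as many genes as the 0 (highest other 216) and 7 of 10 as many lists as the 8 (highest other 13). For the control time course, 1 of 10 gave as many genes as the 2314 (highest other 0) and 6 of 10 as many lists as the 10 (highest other 15). With array quality weights the Fk counts were 156 at 12 h (highest other 3), 94 at 48 h (highest other 2521, a structure of the samples) and 527 over both times, a count that 10 of 100 regroupings reached (highest other 1210).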

How the results depend on the processing

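The settings chosen after seeing the data were the spike-in covariate and the fits that combine 2 choices below. Of the results followed, 4428 of single genes kept their direction and their side of the threshold, 236 became weaker, 65 stronger and 53 changed sign, 51 of them past the threshold in neither setting. Of list results, 750 were the same, 57 weaker and 3 reversed. Of counts and correlations, 236 stayed the same and 65 moved. Unless named, the cause was not tested. Whether low signal limits the calls of dim genes was not separated from the number of genes tested.

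Leaving out one array gave 0 to 3 genes at 12 h, 0 to 1 at 48 h, 0 to 2 over both times, 0 to 1 called at both times and 1060 to 3438 in the control time course. It gave 4 to 11 lists at 12 h, 7 to 14 lists for the difference, and correlations of the effects from 0.0223 to 0.256. At 12 h the values ran from -0.17 to 0.071 for FKBP5, -0.34 to 0.54 for CCN2, -0.43 to 0.36 for GDF15, -0.40 to 0.12 for HAVCR1, -0.36 to 0.024 for LCN2, -0.41 to -0.0060 for CDKN1A, 0.35 to 0.96 for HMOX1, 0.20 to 1.68 for DDIT3 and 0.22 to 0.63 for HSPA5. At 48 h they ran from -0.67 to 0.10 for HAVCR1, -0.21 to 0.99 for LCN2, -0.068 to 0.13 for CLU, -0.56 to 0.55 for CCN2, -0.51 to 0.37 for RCAN1, -0.13 to 0.10 for FKBP5, -0.23 to 0.20 for HMOX1, -0.47 to 0.19 for DDIT3, -0.36 to 0.30 for HSPA5, 0.10 to 0.45 for CDKN1A, 0.30 to 0.53 for GDF15 and -0.063 to 0.49 for CXCL8. The DNA replication median at 48 h ran from -0.43 to 0.12.

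With no filter on dim probe sets there was 1 gene at 48 h, 0 over both times and 15 lists for the difference; with the filter at log2 6 there was 1 gene at 48 h. Quantile normalization gave GDF15 at 12 h 0.0077 and HSPA5 at 48 h 0.022, and centring gave CCN2 at 12 h -5.8e-04. The mean of all probe sets gave 4 genes at 48 h and 2 over both times, GDF15 at 12 h 0.0043, and at 48 h RFC5 0.10, CLU -0.036, RCAN1 0.046, FKBP5 0.019 and HSPA5 0.12. With trend and robust moderation 0 genes passed over both times. Array weights gave 156 genes at 12 h, 94 at 48 h, 527 over both times, 7 at both and 4920 in the control time course, HAVCR1 0.035 and GDF15 0.31 at 12 h, and RCAN1 0.37, HMOX1 0.0090, CXCL8 -0.22 and CCN2 0.42 at 48 h. An adjusted p under 0.01 left 0 genes over both times and 768 in the control time course, and a log2 fold change of at least 1 left 941 there. Camera with an estimated correlation called 0 lists at 12 h, 0 at 48 h, 0 for the difference and 0 for the control time course, and fry called 0 for each of the first 3 and 7 for the control time course (smallest adjusted p = 3.2e-04). For changes in either direction, fry called 0 lists at 12 h, 3 at 48 h, 0 for the difference, 1 over both times (HIF targets, adjusted p = 0.0307) and 28 for the control time course.

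The reported tests did not pair the arrays by replicate number, since not every pair of same-numbered arrays deviated together. At 48 h this reason does not argue against pairing, since same-numbered arrays lay together there. Deviations of same-numbered arrays correlated at 0.041, 0.265 and 0.163 at 12 h and at 0.798, -0.025 and 0.606 at 48 h. On the first principal component, replicates 2 at 48 h (34.3 and 36.4) lay between replicates 1 (56.1 and 51.2) and 3 (13.3 and 10.2). Their low correlation therefore says little against pairing. Tests without a block may carry spread that same-numbered arrays share at 48 h, and leaving out a single array leaves its partner unmatched. The replicate block gave 0 genes over both times, and the replicate block within time gave 1 gene at 12 h, INHBE at 3.07 (adjusted p = 0.0149), 0 over both times and 15 lists for the difference. It had 1264 genes at an unadjusted p under 0.05 at 12 h and 983 at 48 h. The replicate block within time without Fk_12h replicate 3 gave 3 genes at 12 h, 4 at 48 h, 4 over both times, 1 at both, 11 lists at 12 h, a correlation of 0.319, and at 12 h HAVCR1 0.079 and GDF15 0.25. A fit to only the groups of the comparison gave 1 gene at 48 h, SLC16A14, with 554 genes at an unadjusted p under 0.05. With a replicate block it also gave SLC16A14 alone, with 1300 such genes, and without Fk_12h replicate 3 it gave 1 gene and 11 lists at 12 h, HAVCR1 0.12 and GDF15 0.36. The poly-A spike-in covariate gave 0 genes over both times, 15 lists at 12 h, a correlation of 0.387, at 12 h HAVCR1 0.15, GDF15 0.070, RCAN1 -0.32, HMOX1 -0.037 and HSPA5 -0.13, and at 48 h LCN2 -0.050, CLU -0.013, CCN2 0.22 and a DNA replication median of 0.0086.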

Other observations

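The genes in this part were named after the results of the control time course were seen. In control cultures at 48 h against 12 h, further genes differed in lists that were not called. GDF15, a stress-induced cytokine gene, rose by 2.46 ± 0.35 (SE, n = 3 per group, limma adjusted p = 0.00196), and the p53 target GADD45A rose by 2.21 ± 0.36, while the list of p53 targets, with 4 of 22 members risen and 2 fallen (4 and 2 adjusted over the list alone), was not called (camera adjusted p = 0.288). Of 20 NF-kB and inflammatory cytokine genes 4 fell and 0 rose (the same counts adjusted over the list alone, limma), among them the chemokine gene CXCL5 at -2.46 ± 0.44 and the cytokine gene IL32 at -1.05 ± 0.20, and this list was not called either (adjusted p = 0.109). CCND3, a G1 cyclin gene, fell by 1.17 ± 0.19. Glycolysis genes had a median of -0.20 and a mean of +0.04, of opposite signs, and were not called (adjusted p = 0.807).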
